A study of Homo sapiens with 18 samples.

How the data were processed

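The series holds 18 libraries, 9 immunoprecipitated with an antibody against H3K36me2 and 9 inputs, from BHT-101 cells and 2 ASH1L knockout clones in 3 replicate experiments. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min, chromatin was sheared to 200 to 600 bp, and libraries were read with 50 nt single-end reads in shared lanes. The protocol speaks of 4 knockout samples, while the labels name 2 clones, and those alone were analysed here. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.1, aligned to hg38 with Bowtie2 2.2.9, and peaks were called with MACS2.

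The deposited files are 9 broad peak lists, each from a single immunoprecipitated library and its input, with no pooling of replicates. Each deposited peak has a position, a fold enrichment over input and a −log10 p and −log10 q. The integer score was not used here. The lowest −log10 q lay near 1.3 in every list, so the authors kept peaks at a q of 0.05. The fold and significance of a peak belong to its own list and were used only to describe, rank or filter peaks within it. Numbers of reads were not used here, so the depth of each library is unknown, and its effect on the length of a list could not be removed directly.

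From the lists, the covered length, the number of peaks, the share of covered length inside protein-coding gene bodies, the share per chromosome and the Jaccard index of each of the 36 pairs of lists were computed. Gene positions came from a RefSeq gene table of GRCh38.p14, the same build, which holds 19974 protein-coding genes on chromosomes 1 to 22 and X and gives no strand, exons or UTRs. Whether a peak lies in an exon or an intron is therefore not given, and analyses that need the start of a gene were not run. For each gene of at least 5 kb the percent of the body covered was taken, and 4303 genes with a mean of at least 1% over the 9 lists were tested.

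The percent covered was compared with limma 3.58.1 (lmFit and eBayes in R 4.3.3) in a single fit of the 3 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05, for both clones against WT, each clone against WT, and the clones against each other. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with the correlation estimated. Values of a whole list were compared by two-sided exact permutation tests over the 84 ways to pick 3 WT lists out of 9 or the 20 for 3 against 3. The mean overlap within genotypes or within experiments was compared one-sidedly with the 280 partitions into 3 groups of 3. Correlations over lists used all 362880 pairings. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used otherwise.

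The designs, gene lists and most alternatives were fixed before the data were examined. The named genes are ASH1L, then the 10 genes lower and the 10 higher with the largest moderated t among those that moved the same way in all 6 differences between a clone and the WT list of its experiment, since none passed the threshold, and up to 4 members of each gene list by the same statistic. Genes named from the fit after quantile normalization outside this rule were chosen after their values were seen. Alternatives were only peaks with −log10 q of at least 3, equal covered length (the strongest peaks of each list up to 10.19 Mb), a logit scale with an offset of 0.01, quantile normalization, no filter on mean or length, other coverage minimums and windows, and each list or experiment left out. Gene ends within 2500 bp, subtraction of the coverage of flanks, the replicate block with quantile normalization, the chromosome shares and the counts of genes moving alike in all experiments were added after the data had been seen.

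The experiment number pairs the lists by the labels, which speak of replicate experiments. As a check, the correlation of deviations from the group means between lists of the same experiment ranged from -0.265 to 0.254 over 9 pairs. The interval arithmetic was tested on simulated data, with 0 mismatches in 1100 checks. The fits were tested for both clones against WT on 4303 simulated genes. In the same simulated data 100 genes lost 15 points and 100 others lost 30 points. The changed genes were drawn from those with a normalized mean of at least 15%, and their losses were scaled with the length of each list. On the scale as called, 0% of losses of 15 or 30 points were recovered. After quantile normalization 47% and 80% were recovered with 13 unchanged genes called, and without differences in list length 53% and 82% with 10.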

Results

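Dimethylation of histone H3 at lysine 36 (H3K36me2) was mapped by chromatin immunoprecipitation and sequencing in BHT-101, a cell line from an anaplastic thyroid cancer, and in 2 clones of it that lack ASH1L, a histone methyltransferase of the Trithorax group that acts on this residue. In clone 1 both alleles carry a stop after amino acid 413, and in clone 4 the stops lie after amino acids 2169 and 2174. Wild type (WT), clone 1 and clone 4 were each measured in 3 biological replicate experiments, numbered alike across the groups, which gave 9 peak lists, each called against its own input library. The lists held between 7529 peaks (WT, experiment 3) and 78738 peaks (WT, experiment 2), and the genome they covered ranged from 10.19 Mb to 252 Mb in those lists. Numbers of reads were not used here, so the depth behind each list is unknown and no interval for counting error is given. The unit of comparison for a gene is the percent of its body covered by peaks, on the hg38 build.

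The first question was whether loss of ASH1L altered how much of the genome was called as enriched in H3K36me2, and where. Peaks covered 107 Mb ± 127 (SD, n = 3) in WT, 62.8 Mb ± 56.8 (n = 3) in clone 1 and 107 Mb ± 43.3 (n = 3) in clone 4. Protein-coding gene bodies held 39.6% ± 10.1 (SD, n = 3) of the covered length in WT, 31.0% ± 4.58 (n = 3) in clone 1 and 34.4% ± 5.12 (n = 3) in clone 4, beside the 41.6% of the annotated genome that these genes occupy. Covered length in the 6 knockout lists differed from WT by 0.33 on the log2 scale (two-sided exact permutation p = 0.810), and the number of peaks by 0.58 (exact p = 0.536), with replicates of WT alone spread more widely. The intragenic share differed by -6.87 percentage points (exact p = 0.179). Without WT replicate 3, the shortest list, the difference in covered length was -0.87, that in peaks was -0.33, and the intragenic share differed by -11.5 points (exact p = 0.0357, the smallest that the 28 splits of 8 lists allow). The smallest p that the 84 splits of all 9 lists allow is 0.0119, and 3 lists against 3 cannot go below 0.1.

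Longer lists held wider and weaker peaks with more of their length in genes. Across the 9 lists the intragenic share went with the log2 of the covered length (Pearson r = 0.780, exact permutation p = 0.0105; Spearman rho = 0.8, exact p = 0.0138). The authors' median fold enrichment went the other way (r = -0.887, exact p = 0.000752; rho = -0.883, exact p = 0.00308), and the median width rose with the length (r = 0.865, exact p = 0.000728; rho = 0.983, exact p = 4.96e-05). The adjusted p of these 3 relations were 0.0105, 0.00113 and 0.00113. Without the 2 lists farthest from the median length, r was 0.809, -0.761 and 0.975. When every list was reduced to its strongest peaks up to the 10.19 Mb of the shortest list, the intragenic share was 28.4% ± 1.77 (SD, n = 3) in WT, 26.5% ± 2.52 (n = 3) in clone 1 and 27.2% ± 3.56 (n = 3) in clone 4, and the knockout lists differed from WT by -1.47 points (exact p = 0.452).

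**Figure D1:**
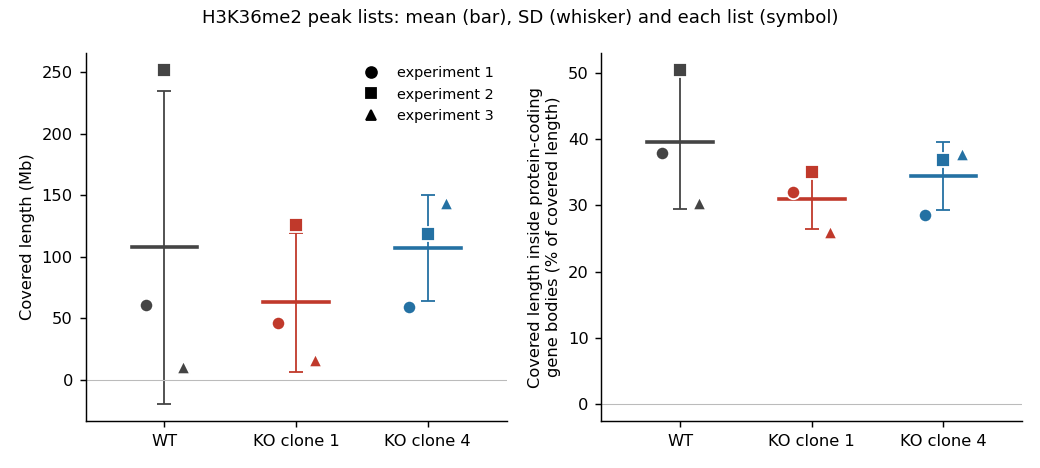
Covered length in Mb (left) and percent of the covered length inside protein-coding gene bodies (right) for each of the 9 peak lists, with the mean (bar) and SD (whisker) of each group and a symbol per experiment. Covered length ranges from 10.19 to 252 Mb within WT alone, wider than the differences between the group means of 107, 62.8 and 107 Mb.

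Enriched regions of clone 1 stood apart from those of WT and clone 4, which were not separated from each other in the same way. The Jaccard index, shared over combined bases, averaged 0.160 between lists of the same genotype, 0.117 between lists of the same experiment and 0.0999 between lists that shared neither. Over the 280 partitions of the lists into 3 groups of 3, the mean within genotypes had a one-sided exact p of 0.00714. The mean within experiments had one of 0.482, and the difference between these means was not tested. Between groups, WT and clone 4 shared the most (0.162), more than the WT lists among themselves (0.122) and above WT with clone 1 (0.0684) and clone 1 with clone 4 (0.0867). At equal covered length the index within genotypes was 0.120 (exact p = 0.00357), with 0.174 among the WT lists, 0.0832 in clone 1 and 0.104 in clone 4, and WT with clone 4 at 0.104 as well. In that setting 7 of the 9 lists were nearest to another list of their own genotype, and the other 2, both of clone 4, were nearest to WT replicate 2. With peaks of -log10 q of at least 3 alone, same-genotype lists no longer exceeded same-experiment lists (difference -0.000717). The mean within genotypes then had a one-sided exact p of 0.289. That setting left 30 peaks in WT replicate 3 and 31 in clone 1 replicate 3, against 2882 in WT replicate 2. Overlaps of such short lists say little about genotype. Without clone 4 replicate 3, with peaks as called, the difference was -0.00295.

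**Figure D2:**
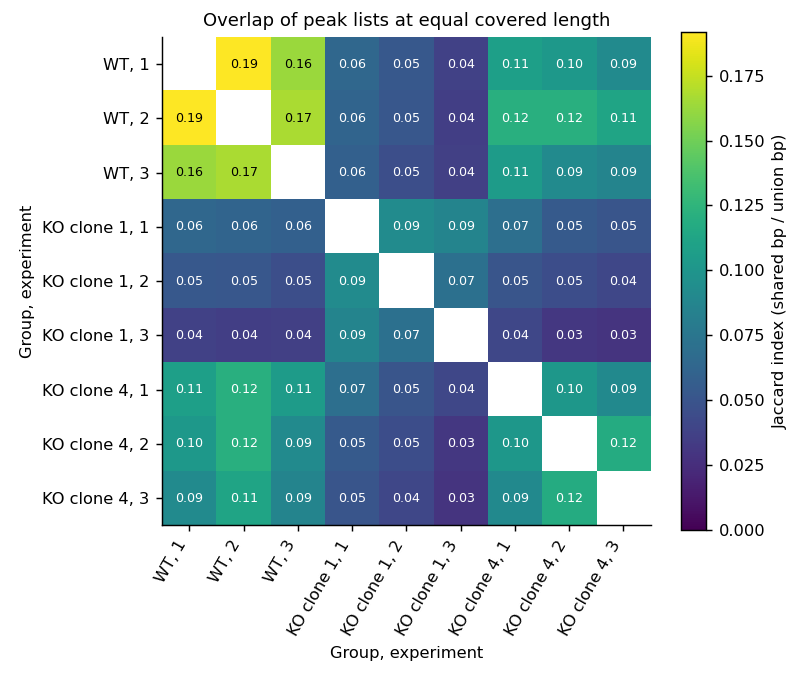
Jaccard index (shared bases over combined bases) for each pair of the 9 peak lists, every list reduced to its strongest peaks up to 10.19 Mb, with groups and experiments along both axes. WT lists share the most with each other (mean 0.174), and clone 1 shares little with WT (0.0494) or with clone 4 (0.0458).

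Enriched regions were spread differently over the chromosomes in clone 1. Chromosome 1 held 10.21% ± 0.918 (SD, n = 3) of the covered length in WT, 3.67% ± 0.474 (n = 3) in clone 1 and 8.42% ± 0.422 (n = 3) in clone 4, and chromosome 2 held 5.28% ± 3.02, 0.965% ± 0.730 and 5.98% ± 2.14. Chromosome 4 held 4.30% ± 2.15 in WT, 16.6% ± 2.89 in clone 1 and 5.83% ± 0.296 in clone 4 (n = 3 each). On the long arm of chromosome 1 beyond 160 Mb, the 3 WT lists placed 5.42%, 5.2% and 4.70% of their covered length, the clone 4 lists 4.46%, 3.07% and 3.91%, and the clone 1 lists 0.0910%, 0.343% and 0.0321%. The chromosome shares were compared only after the data had been seen. For both clones against WT, none of 23 chromosomes passed an exact permutation test with Benjamini-Hochberg adjustment as called (lowest adjusted p = 0.137, 9 lists, with 6 chromosomes at an unadjusted p under 0.05), and each clone alone against WT gave p of at least 0.1, the smallest that 3 against 3 allows in an exact test.

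At equal covered length 6 chromosomes passed for both clones against WT, each at an adjusted exact permutation p of 0.0456. Within experiments none passed, since each of the 6 had an exact p of 0.0370, the smallest that 27 relabellings allow, and an adjusted p of 0.142. The share of chromosome 7 fell from 16.5% ± 1.88 (SD, n = 3) in WT to 5.09% ± 1.60 in clone 1 and 10.3% ± 2.43 in clone 4, that of chromosome 1 from 8.47% to 2.94% and 5.12%, and that of chromosome 12 from 7.38% to 3.35% and 5.03%. The X chromosome fell from 0.804% to 0.453% and 0.503%. Chromosome 9 rose from 0.324% to 2.30% and 2.41%, and chromosome 14 from 1.76% to 3.26% and 2.93%. Each of these shares lay on the same side of WT in all 6 clone lists. The lists are repeats of WT and 2 clones, so the test cannot tell loss of ASH1L from other stable differences of the clones. Shares also depend on each other, and in this setting chromosome 4 held 1.65% in WT, 15.5% in clone 1 and 3.30% in clone 4.

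**Figure D3:**
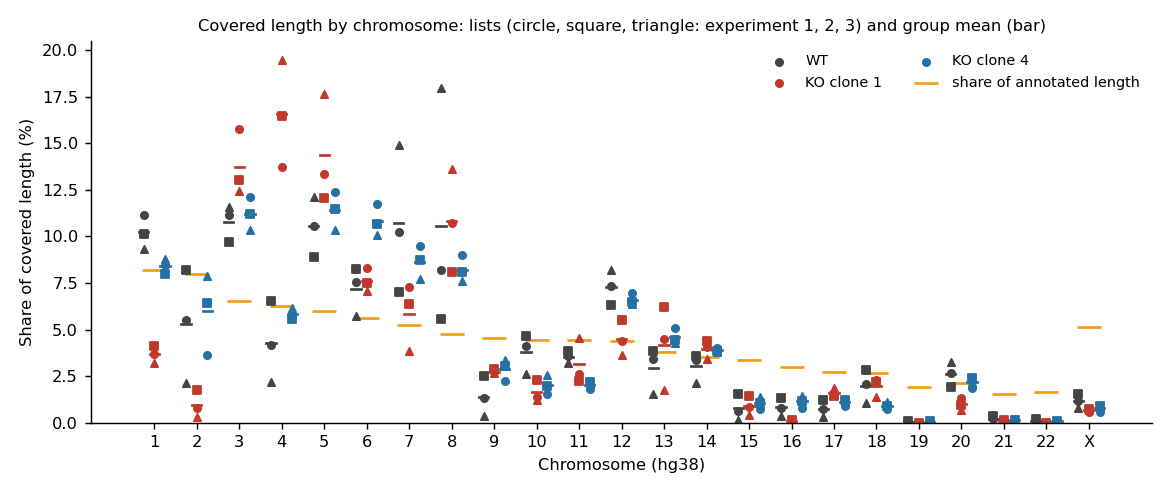
Share of each list's covered length (%) on each chromosome, with a symbol per experiment, a bar for the group mean and, in orange, the share of the annotated genome length on that chromosome. Clone 1 lies below WT on chromosomes 1 and 2 (3.67% against 10.21%, and 0.965% against 5.28%) and above it on chromosome 4 (16.6% against 4.30%).

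**Figure D4:**
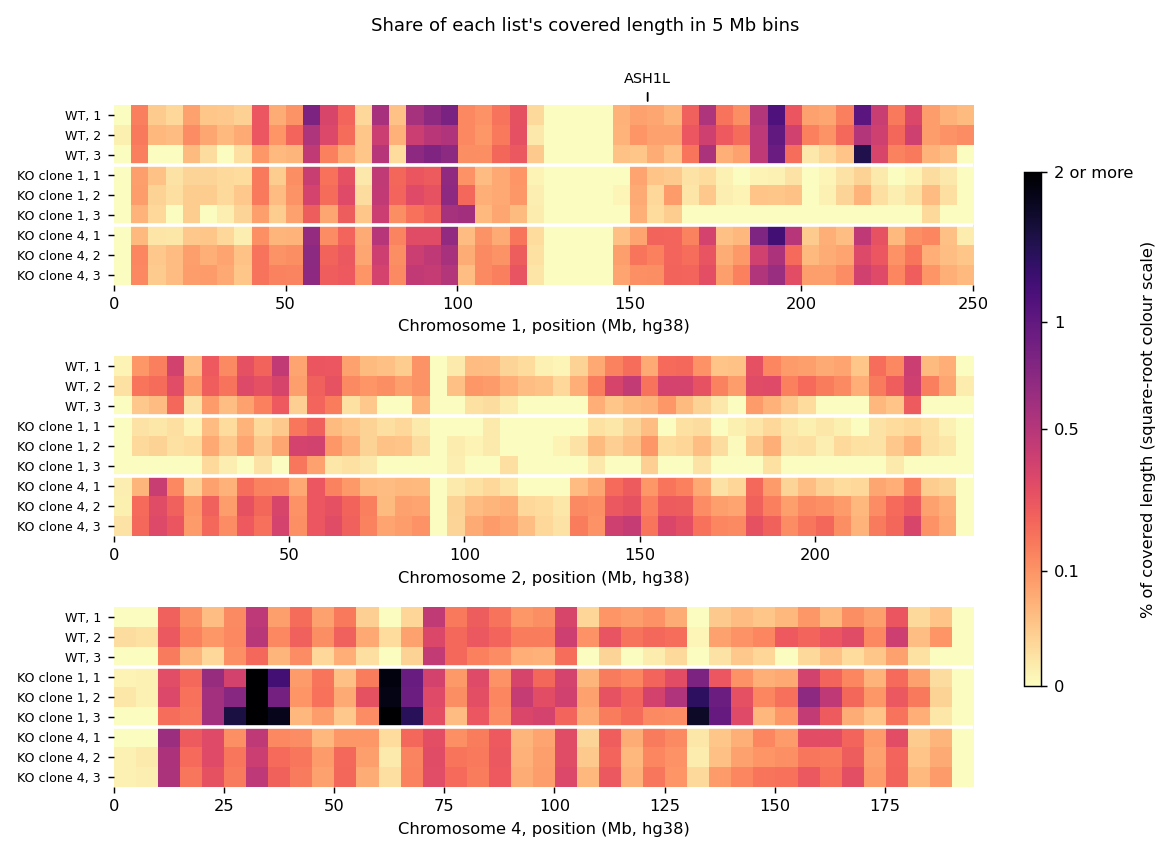
Percent of each list's covered length in bins of 5 Mb (square-root colour scale) along chromosomes 1, 2 and 4, with a line per list, lists grouped by genotype and the position of ASH1L marked. Beyond 160 Mb on chromosome 1 the clone 1 lists hold 0.0910%, 0.343% and 0.0321% of their length, against 5.42%, 5.2% and 4.70% in WT.

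Gene by gene, the comparison of both clones with WT asked which gene bodies lost or gained called H3K36me2. ASH1L itself (chromosome 1, 155335268 to 155563202) was covered over 2.27%, 18.3% and 0.135% of its body in the 3 WT lists, over 0%, 0.387% and 0% in clone 1, and over 0%, 1.16% and 1.93% in clone 4. These values give no check of the genotype, since a mark on the gene body is not its product. Of the genes lower in both clones in every experiment, TMEM45B (chromosome 11, 129815848 to 129860003) was covered over 10.3% ± 6.46 (SD, n = 3) in WT and 0% in all 6 clone lists. HGF, which encodes the ligand of the MET receptor (chromosome 7, 81699010 to 81770047), was covered over 21.7% ± 17.6 in WT, 5.03% ± 5.54 in clone 1 and 0% in clone 4, and DUSP10, a phosphatase of stress-activated kinases (chromosome 1, 221701424 to 221742089), over 20% ± 24.5, 0% and 1.01% ± 1.74. DUSP10 lies beyond 160 Mb on chromosome 1, where the clone 1 lists placed only 0.0910%, 0.343% and 0.0321% of their covered length. Its 0% in clone 1 cannot be told apart from the low coverage of that whole segment. KMT2E, a Trithorax relative, was covered over 8.61% ± 5.09, 1.68% ± 2.91 and 1.02% ± 0.888. Of the genes higher in both clones in every experiment, DNASE2B (chromosome 1, 84398484 to 84415018) was covered over 0% in the WT lists, 34.9% ± 18.6 in clone 1 and 45.2% ± 5.63 in clone 4.

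The other genes came from the same rule, fixed before the data were examined. It admits only genes that moved alike in all 6 differences, so their shared direction follows from the choice. Those lower in both clones were PEX2, a peroxisome assembly factor (21.5% ± 17.3 in WT, 6.96% ± 8.86 in clone 1, 0% in clone 4), TES (17.2% ± 16.6, 2.12% ± 1.84, 1.72% ± 1.77), KLRC1 (35.5% ± 4.73, 19.4% ± 11.0, 18.4% ± 16.2), EPHX1, ARHGEF12 and TASOR2. Those higher were SNTG1, a syntrophin (4.36% ± 4.63, 42.6% ± 8.62, 10.4% ± 1.64), CDH9, a cadherin (0% in WT, 52.5% ± 26.5, 5.05% ± 1.25), NOS1AP (0%, 4.49% ± 5.44, 22.3% ± 9.11), RELN, which encodes the secreted glycoprotein reelin (1.86% ± 1.67, 6.61% ± 6.42, 17.1% ± 3.89), SLCO1B1, a hepatic anion transporter (0%, 25.1% ± 16.6, 12.3% ± 4.77), the neighbours SUN3 and C7orf57, TLCD4-RWDD3 and CCDC152. Like DUSP10, EPHX1 lies beyond 160 Mb on chromosome 1, where clone 1 lists held little covered length, while NOS1AP in the same segment was higher. None of the 4303 genes tested passed limma at an adjusted p of 0.05 on the lists as called (64 genes at an unadjusted p under 0.05), and each of these 20 genes had an adjusted p of 0.625. At 6 of them, and by its WT values at EPHX1, much of the difference rested on WT replicate 2. Without it the difference was -5.62 in place of -19.5 points at DUSP10 and -9.18 in place of -19.2 at HGF. It was -9.52 in place of -18.1 at PEX2 and -6.02 in place of -15.3 at TES. At ARHGEF12 it was -3.18 in place of -12.8, and at TASOR2 -3.23 in place of -11.6. The spread of list lengths may contribute to this limit. In simulated data with that spread the same fit recovered 0% of gene bodies given a loss of 30 points, against 82% without it. List length was the only difference between lists built into the simulation besides noise, so it cannot show what set the limit in the real lists.

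**Figure D5:**
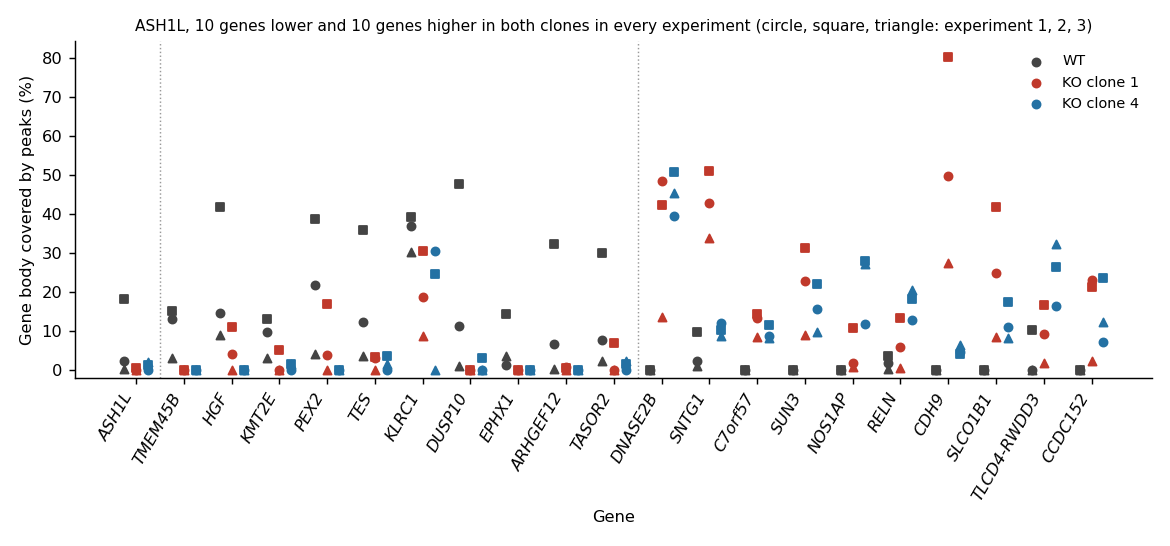
Percent of the gene body covered by peaks in each of the 9 lists (symbols, by experiment) for ASH1L, for 10 genes lower and for 10 genes higher in both clones in every experiment. DNASE2B is at 0% in the 3 WT lists and at 34.9% ± 18.6 and 45.2% ± 5.63 in clones 1 and 4, while WT values of the lower genes spread widely between experiments, as for HGF at 21.7% ± 17.6.

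After quantile normalization across lists, an alternative chosen before the data were examined, 149 genes fell and 188 rose in the mean of both clones against WT, a contrast that a change in 1 clone can carry. The following genes were picked from that fit after their values were seen. Differences given after quantile normalization, here and below, are points on the normalized scale, which differ from measured percent of the gene body. MMP20, a matrix metalloproteinase of tooth enamel, fell by 39.4 ± 4.19 (SE) points (adjusted p = 0.00158), RGS13, a regulator of G protein signalling, by 35.6 ± 3.09 points (0.000709), and MAML2, a coactivator of Notch signalling, by 24.7 ± 1.96 points (0.000564). CD36, a fatty acid transporter, and SEMA3C, a secreted semaphorin, fell as well. CD69, an activation antigen of lymphocytes, rose by 46.4 ± 9.25 points (0.0209), DNASE2B by 42.1 ± 5.13 points (0.00257) and CDH9 by 38.0 ± 3.57 points (0.000957). Among the named genes PEX2, TES, DUSP10, ARHGEF12 and TASOR2 fell in this fit, and DNASE2B, SUN3, NOS1AP, CDH9, SLCO1B1, TLCD4-RWDD3 and CCDC152 rose. Taken separately, DUSP10, ARHGEF12, DNASE2B, NOS1AP and TLCD4-RWDD3 passed in each clone. The genes SUN3, CDH9, SLCO1B1 and CCDC152 passed in clone 1 alone and PEX2 in clone 4 alone, while TES and TASOR2 passed in neither. As called, limma gave 0 genes with a replicate block, 6 on the logit scale and 4 at equal covered length. On the lists as called, 10 of the 149 genes were lower and 60 of the 188 higher in both clones in all 3 experiments. Without WT replicate 1 the count was 202 in place of 337, and without experiment 1, 2 or 3 it was 127, 55 or 300. In simulated data this fit recovered 47% of 100 losses of 15 points and 80% of 100 losses of 30 points, with 13 unchanged genes also called.

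Clone 1 against WT differed at more genes than clone 4 against WT after quantile normalization. CDH9 rose by 70.4 ± 4.12 (SE) points after quantile normalization (adjusted p = 6.77e-05). Its body was covered over 49.8%, 80.3% and 27.5% in clone 1 and 0% in WT, a measured difference of 52.5 points. ABI3BP, TECRL and DTHD1 rose likewise, by 53, 49.6 and 47.4 points. CD36 fell by 53.4 ± 5.63 points (0.000775), from 92.8%, 100% and 58.6% in WT to 10.8%, 32.2% and 0.389% in clone 1, and RGS13 and SLC2A2, a glucose transporter, fell by 49.9 and 43.0 points. In all, 241 genes rose and 185 fell in that fit. Covered length in clone 1 differed from WT by -0.24 on the log2 scale (exact permutation p = 0.9) and the intragenic share by -8.58 points (exact p = 0.3). As called, limma gave 0 genes (106 at an unadjusted p under 0.05). Without experiment 1 or 2 the normalized count of 426 was 281 or 126, and the count as called was 7 without clone 1 replicate 3.

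In clone 4 against WT, CD69 rose by 66.6 ± 10.7 (SE) points after quantile normalization (adjusted p = 0.0133), MTSS1 by 37.9 ± 2.10 points (0.000500), SEMA3A, a repulsive axon guidance cue, by 31.2 ± 5.86 points (0.0249), and STEAP4, a metalloreductase, by 27.9 ± 2.35 points (0.00107). MMP20 fell by 37.1 ± 4.84 points (0.00656), MAML2 by 24.3 ± 2.26 points (0.00155), and CDK6, a kinase of the G1 phase of the cell cycle, by 19.7 ± 2.90 points (0.0108). Covered length in clone 4 differed from WT by 0.90 on the log2 scale (exact permutation p = 0.7) and the intragenic share by -5.17 points (exact p = 0.4). In that fit 141 genes rose and 77 fell, and as called limma gave 0 genes (119 at an unadjusted p under 0.05). The normalized count of 218 was 111 without clone 4 replicate 2, 121 without WT replicate 1, 143 without WT replicate 2, and 17, 1 and 88 without experiments 1, 2 and 3. The count as called was 25 without clone 4 replicate 1, 6 without WT replicate 2, and 1 without clone 1 replicate 3 or clone 4 replicate 2.

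Set directly against each other, the clones differed at 473 genes after quantile normalization, 208 higher and 265 lower in clone 1. CDH9 was higher in clone 1 by 64.8 ± 4.12 (SE) points, and IBSP, SLC2A2 and CD36 were lower by -46.3 ± 3.28, -41.7 ± 2.96 and -45.2 ± 5.63 points. As called, limma gave 0 genes (213 at an unadjusted p under 0.05), 26 without clone 4 replicate 1, 14 without WT replicate 2 and 1 without clone 4 replicate 2. The normalized count was 282 without clone 4 replicate 3, 312 without clone 4 replicate 2, and 299, 103 and 306 without experiments 1, 2 and 3.

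The shift from WT in clone 1 and that in clone 4 were compared across the 4303 genes, which are not independent replicates. The correlation was 0.458, beside 0.430 in groups simulated without an effect against the same WT lists, and the covariance was 28.6 beside 16.9 ± 21.0 (SD of 100 simulated draws). After quantile normalization the correlation was 0.353 beside 0.496, and the covariance 15.7 beside 6.27 ± 3.32. Of the genes called in each clone separately in that fit, 59 fell in both, such as MMP20 and MAML2, beside 3.31 for independent lists of 185 and 77 genes, and 31 rose in both, such as DNASE2B, beside 7.90 for lists of 241 and 141. Opposite calls were made at 2 genes. Both clones were set against the same WT lists, so independent lists are not what no shared change would give, and part or all of the excess may come from these shared controls. Without WT replicate 2 the correlation as called was 0.0111.

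Gene lists fixed before the data were examined asked whether groups with a known role moved together. The clustered protocadherin genes on chromosome 5, cell-surface adhesion molecules of neurons, were at 0% in every WT list and at 4.83% ± 5.85 (SD, n = 3) in clone 1 and 0.441% ± 0.394 (n = 3) in clone 4. They passed camera upward with the preset correlation (adjusted p = 2.32e-13), but the adjusted p was 0.949 with an estimated correlation, and these genes overlap, so that PCDHA3 (9.68% ± 12.2), PCDHA7 (9.70% ± 12.2) and PCDHA8 (9.90% ± 12.5) in clone 1 read the same peaks. None of their 34 tested members passed when adjusted over the list alone, as called or after quantile normalization. The list lost its call without WT replicate 2 or clone 1 replicate 2, where 0 lists passed. Neuronal adhesion and synapse genes passed after quantile normalization alone (adjusted p = 0.0279, and adjusted p = 0.594 with an estimated correlation), in the mean of both clones, with KCNIP4, a potassium channel partner, at 0.448% ± 0.776 in WT, 18.3% ± 16.3 in clone 1 and 9.89% ± 3.19 in clone 4. In that fit 2 of its 10 tested members, KCNIP4 and CDH12, rose, and 3 passed when adjusted over the list alone.

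The means of groups with a chromatin or thyroid role were set largely by WT replicate 2, the longest list, so a lower mean in the clones is not read as a loss. Trithorax and MRG15 partner genes averaged 1.02% ± 1.04 (SD, n = 3) in WT, 0.131% ± 0.226 in clone 1 and 0.162% ± 0.126 in clone 4 (exact permutation p = 0.0476, adjusted p = 0.698 over 22 lists), with KMT2E and KMT2C (7.78% ± 8.72, 0.674% ± 1.17, 2.35% ± 1.69) as its most covered members. At equal covered length the exact permutation p of this list was 0.0119 before adjustment, the smallest that the 84 splits allow. Those of the Polycomb, H3K36, thyroid and TGF-beta lists were 0.345, 0.167, 0.607 and 0.238. The same test gave 0.0238 for p53 and DNA repair genes and 0.0357 each for PI3K and mTOR pathway genes and cell cycle genes. These p were not adjusted over the 22 lists. Polycomb genes averaged 2.98% ± 4.12, 0.487% ± 0.555 and 1.04% ± 0.847 (n = 3 each), from 1.19%, 7.70% and 0.0553% in the 3 WT lists, and EZH2, the catalytic subunit of the Polycomb repressive complex that methylates H3K27, stood at 21.7% ± 23.2 in WT, 1.39% ± 1.4 in clone 1 and 9.29% ± 8.01 in clone 4. H3K36 methyltransferases and demethylases averaged 2.40% ± 3.75, 0.196% ± 0.299 and 0.403% ± 0.475. Thyroid differentiation genes averaged 3.74% ± 4.73, 1.32% ± 1.29 and 3.09% ± 1.5, from 1.98%, 9.09% and 0.133% in the 3 WT lists, with the thyroid hormone receptor THRB at 37.9% ± 36.6, 4.18% ± 4.32 and 37.3% ± 15. TGF-beta pathway genes averaged 6.04% ± 8.06, 1.05% ± 1.09 and 3.11% ± 2.12. HOX cluster genes had their highest mean in clone 4, with 0.140% ± 0.242, 0.0578% ± 0.0501 and 0.745% ± 0.835, and HOXA3 was at 0% in WT, 2.25% ± 1.95 in clone 1 and 7.92% ± 5.43 in clone 4. After quantile normalization EZH2, THRB, BRAF, a kinase of the MAPK pathway, LRP6, a Wnt coreceptor, CDK6 and COL5A2, a fibrillar collagen, fell in the mean of both clones against WT, with adjusted p of 0.0157, 0.0401, 0.00676, 0.00995, 0.00629 and 0.0369, and INHBA, a subunit of activin, rose (0.00496). Taken separately, BRAF and CDK6 passed in each clone (adjusted p = 0.0408 and 0.0108 in clone 4). The genes EZH2, LRP6, THRB and COL5A2 passed in clone 1 alone (adjusted p = 0.0726, 0.0726, 0.956 and 0.995 in clone 4), and INHBA in clone 4 alone (0.999 in clone 1). None of the 22 lists had a member past the threshold as called, adjusted over the list alone.

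None of the remaining lists passed the exact permutation test of its mean after adjustment over the 22 lists. Camera was not run for keratin genes, with 2 tested members, or ribosomal protein genes, with 0. The others did not pass camera, as called or after quantile normalization. Mean coverage in WT, clone 1 and clone 4 was 1.28%, 0.244% and 1.16% for developmental transcription factors, 1.90%, 0.385% and 0.605% for MAPK pathway genes, and 2.69%, 1.48% and 1.24% for PI3K and mTOR pathway genes. It was 4.12%, 1.67% and 3.37% for epithelial-mesenchymal transition genes, 3.95%, 0.623% and 1.41% for Wnt pathway genes, 1.56%, 0.239% and 0.635% for cell cycle genes, and 1.16%, 0.515% and 1.28% for p53 and DNA repair genes. Actin cytoskeleton and focal adhesion genes stood at 2.41%, 0.979% and 1.15%, keratin genes at 2.39%, 0% and 2.72%, and ribosomal protein genes at 0.0283%, 0% and 0%. Genes of other cell types stood at 1.57%, 0.324% and 0.947% for immune markers and at 4.24%, 0.651% and 3.99% for fibroblast and endothelial markers. Olfactory receptor genes stood at 0.282%, 0.0928% and 0.169%, and chromosome 19 zinc finger genes at 0.173%, 0.0489% and 0.0346%.

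The strictest form of loss or gain was coverage in every list of a genotype and none of the other. DNASE2B was the only gene covered over at least 10% in all 6 knockout lists and in no WT list, a count of 1 that 3 of the 84 splits of the lists reached. No gene was covered in all 3 WT lists and in no knockout list. Of the 10 kb windows at least 50% covered, 3 were in every knockout list and no WT list, at chromosome 8, 49110001 to 49130000, where no annotated gene lies and PPDPFL is the nearest protein-coding gene at 33.9 kb, and at chromosome 5, 27230001 to 27240000, 191 kb from CDH9. None was in every WT list and no knockout list, a count that rose to 15 without WT replicate 3. Without clone 1 replicate 3 the gained genes numbered 4 and the gained windows 13, and without WT replicate 2 the gained windows numbered 5.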

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

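The splits of the lists and the tests of list length, copy number, surroundings, few reads and weak immunoprecipitation were all chosen after the results they concern had been seen. At 15 genes clone 1 was lower than WT in all 3 experiments while clone 4 was higher in all 3, which made them stand out, and 0 genes showed the opposite. The difference between clones 1 and 4 was -47.7 points of gene body at CLECL1, -37.7 at ENPP3, -31.9 at FAM110B, -29.9 at MLIP, -29.9 at STEAP1B, -28.7 at BACH2, a transcription factor of B cells, -26.8 at IRAG1, -18.5 at TNNI3K and -18.0 at FPGT-TNNI3K, which overlap. It was -13.6 at TPRG1, -12.0 at BTBD9, -11.7 at CACNA2D1, a calcium channel subunit, -10.9 at CLVS1, -9.63 at CHN2 and -6.12 at LIPK. These differences were not tested in the way they were picked, and limma on the lists as called gave 0 genes between the clones (213 at an unadjusted p under 0.05). After quantile normalization 10 of the 15 differed between the clones in limma, among them FAM110B (adjusted p = 0.000276) and BACH2 (0.00208), while TPRG1 (0.785), BTBD9, CLVS1, CHN2 and LIPK did not pass, but the genes were picked for a difference in the same lists, so this test is no independent support.

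The first pattern weighed is the spread of clone 1 peaks over the chromosomes: of the 29 bins of 5 Mb on chromosome 2, 26 were below WT in all 3 experiments, and of 14 bins on chromosome 1 beyond 160 Mb, 13 were, as a lower copy number of these segments would give. Over all chromosomes 176 of 370 bins were below WT in all 3 experiments, with 5 of 6 on chromosome 16 and 5 of 6 on chromosome X. A high share of lower bins is thus not particular to these segments. An even gain of all of chromosome 4 cannot be told apart from gains in part of it, because 23 of its 33 bins were higher in all 3 experiments (median 0.99 on the log2 scale) and 5 were lower. The share of chromosome 2 in clone 1 differed from WT by -4.32 points as called and by -1.29 points at equal covered length. List length may thus account for part of this difference. At equal length clone 1 stayed below WT in all 3 experiments, which argues against length alone, but depth is unknown and is not excluded in this setting. Loss of ASH1L acting alike in both clones is argued against by the median of the chromosome 2 bins in clone 4, 0.10 on the log2 scale. A break at the edited ASH1L site on chromosome 1 cannot be told apart from other events, because the share before ASH1L was below WT in 3 of 3 experiments with overlapping ranges. A copy-number change in clone 1 may contribute, through the power to detect peaks against each list's own input, as may an effect of ASH1L loss in that clone alone.

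The second pattern is the set of genes called in the mean of both clones against WT after quantile normalization. A shift of whole regions cannot be told apart from changes at these genes, because they were picked as extreme. The lower genes, such as MAML2, moved by a median of -1.84 on the log2 scale and their surroundings by -0.68, and the higher ones, such as CDH9, by 5.27, where WT values of 0% leave the size to the offset, and their surroundings by 0.51, with the same direction in 74.5% and 75.5% of the surroundings. List length cannot be told apart from a difference at these genes, because they were picked for their direction: at equal covered length 91.9% of the lower genes kept it, and so did 99.4% of the 172 higher genes still covered, out of 188. A shared effect of ASH1L loss may account for part of the set, as may a change in clone 1 alone or a difference between cloned and uncloned cells, which the design cannot separate.

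The third pattern is the short WT list of experiment 3. Few reads could give it, since shorter lists held peaks of higher median fold (r = -0.887 over the 9 lists). A weak immunoprecipitation cannot be told apart from this, because its highest fold of 5.11, above that of the 8 other lists, rests on single peaks. No biological explanation was tested.

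Other splits of the lists were counted beside each result from all genes. For both clones against WT as called, 100 of 100 splits reached the real 0, as any split must, so this count does not bear on chance, and another split gave 400, which points to a structure of the samples other than genotype, such as list length. After quantile normalization 1 of 100 splits, the real one, reached 337 genes, and the highest other gave 325. The other splits were drawn at random from all possible ones, so this draw alone does not show that the real split is the highest. Among all 108 splits that keep 1 list of each experiment in each group, 2 reached 337, and the other of them, with clone 1 in the place of WT, gave 491. The count thus reflects that the 3 groups differ and is not specific to WT against the knockouts. Gene lists past the threshold numbered 1 (66 of 100 splits as large, highest other 3) and, after quantile normalization, 2 (22 of 100, highest other 2), so chance is not excluded. For pairs of groups the 10 splits are too few for a share under 0.05. As called the real count was 0 for clone 1, for clone 4 and for the clones against each other, reached by 10 of 10 splits each, as any split must, with a highest other of 0, 136 and 0. After quantile normalization the real counts were 426, 218 and 473, each reached by 1 of 10, with a highest other of 1, 2 and 1.

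Genes covered in every WT list and no knockout list numbered 0 (84 of 84 splits as large, highest other 13), and windows 0 (84 of 84, highest other 57), counts of 0 that any split reaches and that do not bear on chance. The single gene covered in every knockout list and no WT list, DNASE2B, was a count that 3 of 84 splits reached (highest other 3), and the 3 such windows a count that 3 of 84 reached (highest other 8), but within experiments 2 of 27 relabellings reached either count, a share above 0.05, so chance is not excluded. Genes lower in both clones in all experiments numbered 29, which 9 of 27 relabellings within experiments reached (highest other 1325, a structure of the samples again), and genes higher numbered 95, which 3 of 27 reached (highest other 305), so chance is not excluded for either.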

How the results depend on the processing

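The chromosome shares, the counts of genes moving alike in all experiments, gene ends, local background and quantile normalization with the replicate block were chosen after the data were seen. Of the values that answer a comparison, 194 kept their direction and side of the threshold, 70 counts moved, 8 values reversed and 1 became stronger. For single named genes 376 values did not change sides, 25 became stronger, and none reversed. The cause was not tested except where fewer lists or peaks are the setting itself. Reads per library are unknown, so list length stands for depth. The promoter share, the 5′-to-3′ ratio and coverage around gene starts were not run, since the gene table holds no strand, and covered length at equal length is fixed by construction.

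With only peaks of -log10 q of at least 3, the difference in covered length reversed to -0.50, that in intragenic share to 4.68 points, and that in overlap to -0.000717. In that setting 0 genes moved alike in either direction, and 0 genes and 0 windows were in every knockout list and no WT list. At equal covered length 6 chromosomes passed, and of 354 genes tested 33 were lower and 9 higher in all experiments, beside 29 lower and 95 higher of 4303 as called. There, windows numbered 1 for WT only and 1 for knockout only, and genes for knockout only 0. Coverage of at least 1% gave 3 genes for WT only and 16 for knockout only, and at least 50% gave 0 of the latter. With 5 kb windows the counts were 1 and 7, and with 50 kb windows 0 for knockout only.

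Leaving out single lists moved the difference in covered length between -0.87 and 1.44 on the log2 scale, reversed without WT replicate 3, and leaving out experiments between -0.63, reversed without replicate 3, and 1.01. The number of peaks ranged from -0.33, reversed without WT replicate 3, to 1.36, and from -0.15, reversed without replicate 3, to 1.03. The intragenic share ranged from -11.5 points (exact permutation p = 0.0357 without WT replicate 3) to -1.44, and from -11.1 to -3.07. Overlap ranged from -0.00295, reversed without clone 4 replicate 3, to 0.0752, and from 0.0295 to 0.0507. Genes for WT only ranged from 0 to 2 without single lists and 0 to 4 without experiments, windows from 0 to 15 and 0 to 30. Genes for knockout only ranged from 1 to 4 and 1 to 6, windows from 3 to 13 and 4 to 16. Without an experiment, genes lower in both clones ranged from 29 to 1565, and higher from 120 to 220. The correlation of the clones ranged from 0.0111 to 0.724, and from 0.0317 to 0.760.

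For both clones against WT, clone 1, clone 4 and the clones against each other, the limma counts of 0 as called became 337, 426, 218 and 473 after quantile normalization, and 6, 43, 9 and 117 on the logit scale. With the replicate block, quantile normalization gave 253, 394, 144 and 397, while the replicate block without it left 0. Equal covered length gave 4, 13, 0 and 5, gene ends 0, 0, 0 and 3, and local background 0, 1, 3 and 4. Without the filter on mean and length, and with the stricter q, all 4 stayed at 0. Single lists left out gave 0 to 1, 0 to 7, 0 to 25 and 0 to 26, and experiments 0, 0, 0 to 3 and 0 to 3. Gene lists numbered 2 after quantile normalization, with or without the replicate block, 0 with an estimated correlation, and 0 to 2 without single lists or experiments.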

Other observations

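The test of the bins beside ASH1L was chosen after the result was seen. Gene-dense chromosomes tended to hold less of the covered length for their size. Spearman correlations of the share over the annotated share with the genes per Mb ran from -0.556 to -0.211 in the 9 lists. They were taken over 23 chromosomes and were not tested. Windows of 10 kb covered in all 3 lists of a group and in no other list numbered 57 in clone 1, 21 in clone 4 and 0 in WT, and 22 of those in clone 1 lay on chromosome 5, which also holds CDH9 and the protocadherin cluster. Among the 81 other triples of lists the highest number was 17 and the median 0.

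On chromosome 1, the bin from 145 to 150 Mb held on average 0.0446% of the covered length in WT, 0.000243% in clone 1 and 0.0628% in clone 4, while the bin from 150 to 155 Mb, next to ASH1L, held 0.0679%, 0.0639% and 0.116%. After quantile normalization, 149 of 4303 genes were lower in the mean of both clones and 188 higher. The lower genes numbered 26 of 295 tested on chromosome 7, 23 of 293 on chromosome 12, 14 of 181 on chromosome 10, 15 of 204 on chromosome 11, 12 of 285 on chromosome 2 and 20 of 485 on chromosome 1. The higher genes numbered 32 of 402 on chromosome 3, 24 of 326 on chromosome 6, 21 of 267 on chromosome 4, 15 of 208 on chromosome 8, 19 of 346 on chromosome 5, 15 of 295 on chromosome 7 and 16 of 485 on chromosome 1.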
